A study of Rattus norvegicus with 28 samples.

How the data were processed

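Messenger RNA was measured in 28 whole-kidney samples of female rats with 1-colour Affymetrix rat expression arrays, 1 array per sample. Total RNA was extracted with a silica column kit and labelled with biotin by the array maker's protocol, per the labels' protocols. The 4 groups had 7 arrays each and crossed 2 strains, SBN/y and SBH/y, with 2 states, both kidneys present after a sham operation or 1 kidney left after uninephrectomy. The animals were killed at an age of 5 months, 4 months after the operation, per the series' design text. The labels number the samples of a group from 1 to 7 but do not say that each array came from a separate animal, so the p-values measure the spread between these samples.

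The authors deposited 1 table of log2 values, with 1 value for each of 31099 probe sets on each array. GCOS, the scanner software, and RMA are named in the submitters' processing notes, with no version given in the sources used here. RMA corrects the background, quantile-normalizes the probes and summarises each probe set on the log2 scale, so differences in total RNA between samples cannot be seen in such values. Whether all arrays were normalized in 1 run is not given in the sources used here. The array medians of the deposited log2 values lay between 5.72 and 5.77, and the correlation between any 2 arrays over all probe sets lay between 0.985 and 0.997. No 2 arrays held identical values. No scanner files were used here, so background and detection could not be checked probe by probe, and dim probe sets were treated by a filter as an alternative.

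Probe sets were named through the platform annotation, with symbols updated by gene identifier in RefSeq's gene table for the assembly GRCr8. Of the 31042 probe sets left after taking out 57 control probe sets, 20826 had 1 gene symbol, 436 had several and 9780 had none. Symbols of 20758 probe sets were matched by gene identifier, 2 by accession, and 66 kept the platform's name. Probe sets with several or no symbols were tested but not named. A gene with several probe sets was represented by the probe set with the highest mean over all arrays, which gave 14217 genes. No genome sequence was used here, and gene positions in that table served only to order neighbouring genes.

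All choices of this paragraph were made before the data were examined. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on the deposited log2 values, with 1 mean per group fitted to all 28 arrays. The fit gave 6 contrasts, and p-values were adjusted by the Benjamini-Hochberg method over the 31042 probe sets in each, with a threshold of 0.05. Positive strain differences are higher in SBH/y, positive uninephrectomy effects are higher after uninephrectomy, and the interaction is the uninephrectomy effect in SBH/y minus that in SBN/y. The value after ± beside a log2 change is its standard error from limma, and beside a group mean it is the SD of 7 arrays. The genes named were the 8 with the largest rise and the 8 with the largest fall among the called genes of a comparison, up to 4 members of each described gene list with the smallest p, and a panel of 15 kidney genes named whatever their values. Of the panel, 2 genes are not reported here. Gene lists were fixed for 38 cell types and pathways, with 865 measured genes, and tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. For each list the number of members called is given over all probe sets and adjusted over the list alone. Camera with an estimated correlation was an alternative, and where it lost a list's call its adjusted p is given beside the list.

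Single values per array were compared with exact two-sided permutation tests over the 7 arrays against 7, adjusted over the family of 20 such tests. The clock gene score of an array was the mean log2 value, each gene centred on its mean over all arrays, of 3 clock genes that peak together (Bmal1, Npas2 and Clock) and of 9 that peak in the opposite phase with the sign turned, 12 genes in all. The score was defined after the clock genes were seen among the calls.

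The test was checked on simulated data with the real means and residual spread, 31042 probe sets and 200 of them changed. For the uninephrectomy effect in SBN/y, 96% of changes of 0.5 log2 units and 100% of changes of 1 log2 unit were recovered, with 12 false calls. For the interaction the shares were 78% and 99%, also with 12 false calls. A gene list shifted by the simulation passed camera in each of the 6 comparisons, with 0 of the other lists called in 5 of them and 3 in the average over the strains, where lists that share genes with the shifted one were not set apart. In these simulations the probe sets were independent, which real arrays are not.

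Alternatives planned before the data were examined were quantile normalization of the deposited values, median centring of each array, leaving out the dimmest 40% of probe sets, trended and robust variance moderation, array quality weights, only the arrays of the groups compared, the replicate number as a block, 1 probe set per gene, and leaving out each array in turn. Leaving out the 8 arrays numbered 6 or 7, the SD of each array as a covariate, and the clock gene score as a covariate were added after seeing the data. Python 3.11.15 and matplotlib 3.10.9 were used for annotation and figures.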

Results

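Kidney gene expression was measured in female rats of 2 inbred strains, SBN/y and SBH/y, with both kidneys in place after a sham operation or with 1 kidney after uninephrectomy, the surgical removal of a kidney. SBN/y and SBH/y are known as the Sabra strains that resist and that develop salt-sensitive hypertension, and SBH/y is known for protein loss in the urine. Each of the 4 groups had 7 arrays, taken at 5 months of age and 4 months after the operation. The deposited log2 values were on 1 scale across arrays, with medians between 5.72 and 5.77. Signal over background was not measured, so log2 changes from or to a low mean are those of the deposited values and give no exact fold of RNA. Of the 126 genes named, 35 had a group mean below the lowest array median. For Agt, Areg, Atf3, Cd3g, Cdk1, Lcn2, Lgals2, Oas1b, S100a9 and Ube2c this held in all 4 groups. A missing call there, as for Lcn2, does not show that the RNA was unchanged. The number of arrays limits the precision of each value. Most of the called differences lay between the strains, with 5570 of 31042 probe sets called with both kidneys in place and 6663 after uninephrectomy. Uninephrectomy was followed by 2558 called probe sets in SBH/y and by 144 in SBN/y.

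**Figure D1:**
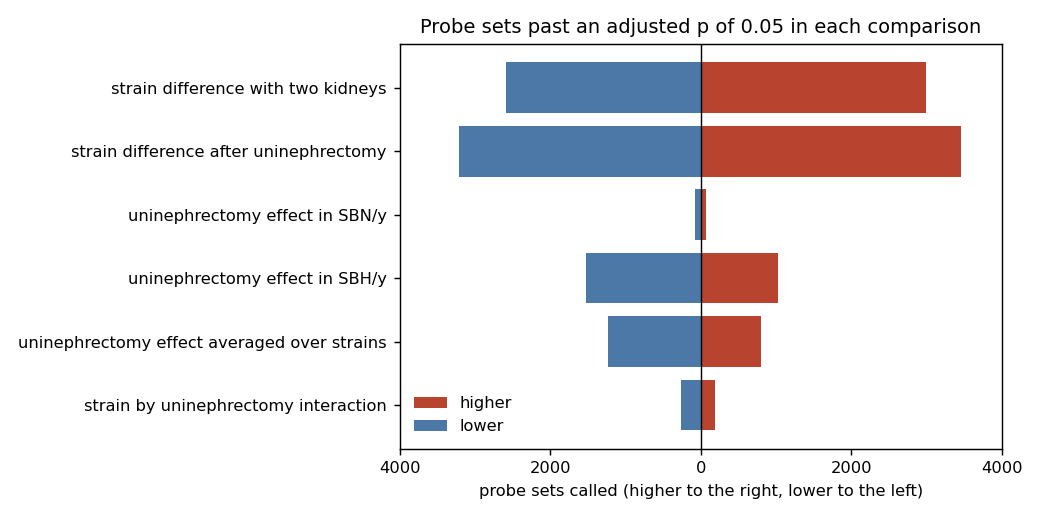
Number of probe sets past an adjusted p of 0.05 in limma (horizontal axis, higher to the right and lower to the left) in each of the 6 comparisons (vertical axis). The strain differences hold 5570 and 6663 probe sets, the uninephrectomy effects 144 in SBN/y and 2558 in SBH/y, their average 2025 and the interaction 439.

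The first comparison asked how the kidneys of the strains differed without loss of renal mass. With both kidneys in place, the value of Mis18a, a factor of centromere assembly, was higher in SBH/y by 2.54 ± 0.08 log2 units (n = 7 arrays per group). Tmed6 was higher by 2.46 ± 0.12, the peroxisomal membrane gene Pxmp4 by 2.39 ± 0.09, Sdf2l1, an endoplasmic reticulum chaperone component, by 2.36 ± 0.08, and Cyp4a1, a fatty acid omega-hydroxylase, by 2.27 ± 0.07. The next largest were Ddit4l at 2.17 ± 0.39, the biliverdin reductase Blvra at 2.15 ± 0.07 and the G protein subunit Gng13 at 2.13 ± 0.12. In the uninephrectomized groups Ddit4l lay apart in the same arrays as the clock gene score, as given below, so clock phase may enter its strain difference. The MHC class II gene RT1-Bb was lower in SBH/y, with a log2 difference of -3.77 ± 0.18, as were Ly6i at -3.62 ± 0.14, the matrix gene Matn1 at -2.94 ± 0.17 and the brown fat uncoupling gene Ucp1 at -2.74 ± 0.38. Lower by a smaller amount were the fatty acid desaturase Scd at -2.02 ± 0.41, Oacyl at -2.01 ± 0.13, the ribonuclease gene Ang at -1.91 ± 0.16 and Bhmt, a betaine methyltransferase, at -1.91 ± 0.13. In limma the adjusted p of these 16 genes lay between 2.85e-21 for Cyp4a1 and 0.000526 for Scd. For part of the strain differences, sequence variants under the probes cannot be told apart from expression, as given below. Over all probe sets, 2991 were higher and 2579 lower in SBH/y, which stood for 1681 and 1378 of 14217 genes, and 147 and 122 probe sets differed by 2-fold or more.

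Of 36 interferon response genes measured, 20 were higher in SBH/y and 0 lower, against 30 higher when adjusted over the list alone (camera adjusted p 1.87e-11, adjusted p = 0.318 with an estimated correlation). Ifi27 was higher by 1.28 ± 0.07 and the antiviral synthetase Oas1b by 1.09 ± 0.08. Macrophage and monocyte markers were higher in 13 of 27 cases and lower in 2 (17 and 2 adjusted over the list alone, camera adjusted p 6.8e-06, adjusted p = 0.352 with an estimated correlation). Lysozyme, Lyz2, differed by 1.04 ± 0.07 and the integrin Itgax by 0.90 ± 0.07. Complement and coagulation genes were higher in 10 and lower in 3 of 28 (12 and 4 adjusted over the list alone), among them C3 at 0.77 ± 0.10 and C1qc at 0.48 ± 0.08. For complement and coagulation the camera adjusted p was 0.0271, against an adjusted p = 0.423 with an estimated correlation. Of 26 genes of antigen presentation, 12 were higher and 5 lower by either adjustment, over all probe sets or adjusted over the list alone (camera adjusted p 0.0271, adjusted p = 0.7 with an estimated correlation). RT1-Ba was higher by 2.02 ± 0.10 and RT1-Db1 by 0.84 ± 0.08, while RT1-CE12 differed by -1.07 ± 0.04. A second probe set of RT1-Ba had a log2 difference of -1.19, called in the opposite direction, and that of RT1-Bb one of -0.07, not called. MHC genes vary in sequence between rat strains, and the probes were not set against the sequences of SBN/y and SBH/y here.

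Genes of mitochondrial oxidative phosphorylation were lower in SBH/y in 26 of 46 cases and higher in 1 (33 and 1 adjusted over the list alone), by small amounts, with a median of -0.11. Examples were Uqcrq of complex III at -0.36 ± 0.05 and Cox5b of complex IV at -0.20 ± 0.03. Cholesterol synthesis genes were lower in 11 of 20 and higher in 1 (13 and 2 adjusted over the list alone), with Idi1 at -0.74 ± 0.12 and Fdps at -0.44 ± 0.06. The adjusted p of camera was 5.37e-09 and 4.38e-05, and for both lists the adjusted p = 0.318 with an estimated correlation.

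Of 12 markers of the thick ascending limb, 6 were lower in SBH/y and 0 higher (7 and 1 adjusted over the list alone, camera adjusted p 0.00126, adjusted p = 0.318 with an estimated correlation). The calcium-sensing receptor Casr differed by -1.12 ± 0.06 and the tight junction gene Cldn16 by -0.46 ± 0.05. Of 14 markers of the distal convoluted and connecting tubule, 6 were lower and 0 higher (8 and 1 adjusted over the list alone, camera adjusted p 0.00126, adjusted p = 0.318 with an estimated correlation). The calcium-binding gene Calb1 differed by -0.86 ± 0.11 and the sodium-calcium exchanger Slc8a1 by -0.70 ± 0.07. Proximal tubule markers were higher in 8 and lower in 1 of 33, by either adjustment, over all probe sets or adjusted over the list alone (camera adjusted p 0.00644, adjusted p = 0.5 with an estimated correlation), led by Agmat at 1.44 ± 0.06 and Cyp4b1 at 1.33 ± 0.09. Sodium and chloride transport, inner medulla, intercalated cell and smooth muscle genes were lower as lists and the unfolded protein response higher, with a camera adjusted p of 0.0107, 0.0264, 0.0342, 0.0363 and 0.0387. With an estimated correlation these lists had an adjusted p = 0.415, 0.656, 0.415, 0.415 and 0.5. Their called members were 11 lower and 2 higher of 33, 6 and 1 of 15, 5 and 0 of 12, 4 and 0 of 17, and 2 and 7 of 28. Adjusted over the list alone the lower and higher members were 13 and 2, 7 and 1, 6 and 0, 4 and 1, and 2 and 7 in the same order. In all, 14 of 38 lists passed the threshold and 0 did so with an estimated correlation, of which 5 had an unadjusted p under 0.05 in camera.

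Of the kidney panel, clusterin, Clu, a gene of tubular stress, was lower in SBH/y by a log2 difference of -0.64 ± 0.07 and Klotho, Kl, by -0.52 ± 0.15. Angiotensinogen, Agt, was higher by 0.41 ± 0.12 and the collagen gene Col3a1 by 0.28 ± 0.10. Their limma calls were lost with 1 array left out, for Agt with SBN/y replicate 6 with both kidneys and for Col3a1 with any of 12 arrays, with log2 differences of 0.33 to 0.46 and 0.21 to 0.33 over all such fits. Havcr1, the kidney injury molecule, differed by 0.15 ± 0.23, the slit diaphragm gene Nphs1 by 0.23 ± 0.10, osteopontin, Spp1, by -0.02 ± 0.10 and Lcn2 by -0.03 ± 0.09, none past the threshold. Umod, Egf, Col1a1, Tgfb1 and Ccn2 were not called either, with differences from -0.17 for Col1a1 to 0.07 for Tgfb1. Adipose tissue markers, which include Ucp1 and Scd, were not called as a list, with 3 lower and 1 higher of 15 (4 and 1 adjusted over the list alone, camera adjusted p 0.454). The lists of adrenal gland, blood, neutrophil and mast cell markers, arachidonate metabolism, glomerular basement membrane, growth factor signalling and vasoactive genes did not pass camera in any of the 6 comparisons.

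The same strain comparison after uninephrectomy called 3454 probe sets higher and 3209 lower in SBH/y, for 2114 and 1694 genes, and 168 and 131 probe sets differed by 2-fold or more. Sdf2l1 was higher by 2.80 ± 0.08, Mis18a by 2.54 ± 0.08, Tmed6 by 2.52 ± 0.12, Havcr1 by 2.40 ± 0.23 (with a mean below the array medians in SBN/y), Pxmp4 by 2.35 ± 0.09, Gng13 by 2.33 ± 0.12, RT1-Ba by 2.14 ± 0.10 and Cyp4a1 by 2.07 ± 0.07. The log2 difference was -3.85 ± 0.14 for Ly6i, -3.71 ± 0.18 for RT1-Bb, -3.41 ± 0.17 for Matn1 and -3.22 ± 0.41 for Nxpe2. It was -2.13 ± 0.09 for the hemidesmosome collagen Col17a1, -2.06 ± 0.06 for Dph6, -1.95 ± 0.14 for the pseudogene Brcc3-ps7 and -1.94 ± 0.06 for the peroxisomal gene Mpv17l. All 16 genes passed the threshold in limma, with an adjusted p of at most 3.09e-07, that of Nxpe2. The limit on sequence variants under the probes holds here too. With both kidneys in place, the second probe set of RT1-Ba went the opposite way and that of RT1-Bb was not called, as given above. Of the probe sets called in this comparison and in the one with both kidneys in place, 3547 went the same way and 24 the opposite way, where independent calls would share 599.4 in the same direction. The log2 differences of the 2 comparisons correlated across all probe sets, which are not independent, with r = 0.808. The group means behind these differences share no arrays, but the calls share a variance per probe set, fitted to all arrays. The number for independent calls is therefore only a rough reference, and the excess over it was not tested.

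Interferon response genes were higher in uninephrectomized SBH/y than in uninephrectomized SBN/y in 28 of 36 cases (30 adjusted over the list alone, camera adjusted p 2.56e-13, adjusted p = 0.11 with an estimated correlation). The transcription factor Irf8 differed by 0.68 ± 0.07. Macrophage markers were higher in 20 of 27 and lower in 2, by either adjustment, over all probe sets or adjusted over the list alone (camera adjusted p 5.52e-10, adjusted p = 0.102 with an estimated correlation). Itgax differed by 1.18 ± 0.07. Tubular injury genes were higher in 16 and lower in 3 of 31 (17 and 3 adjusted over the list alone, camera adjusted p 3.89e-05, adjusted p = 0.141 with an estimated correlation). Gpnmb, a lysosomal glycoprotein of macrophages and injured epithelium, differed by 1.17 ± 0.11 beside Havcr1. Unfolded protein response genes were higher in 14 and lower in 0 of 28 (17 and 1 adjusted over the list alone), with the asparagine synthetase Asns at 1.45 ± 0.08 and the stress transcription factor Atf3 at 0.85 ± 0.07. For unfolded protein response genes the camera adjusted p was 4.27e-06, against an adjusted p = 0.0701 with an estimated correlation. Cell cycle genes were higher in 20 and lower in 1 of 37 (21 and 1 adjusted over the list alone), with the mitotic kinesin Kif11 at 1.28 ± 0.13 and Stmn1 at 0.62 ± 0.05. For the cell cycle the camera adjusted p was 4.5e-05, against an adjusted p = 0.154 with an estimated correlation. Matrix and fibrosis genes were higher in 15 and lower in 1 of 44 (16 and 1 adjusted over the list alone), with the protease Mmp9 at 1.53 ± 0.13 and its inhibitor Timp1 at 0.60 ± 0.08. For matrix genes the camera adjusted p was 0.00244, against an adjusted p = 0.24 with an estimated correlation.

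Among immune lists, antigen presentation genes were higher in 17 and lower in 3 of 26 (17 and 3 adjusted over the list alone, camera adjusted p 1.71e-05, adjusted p = 0.215 with an estimated correlation). Complement and coagulation genes were higher in 14 and lower in 5 of 28 (15 and 5 adjusted over the list alone, camera adjusted p 0.00336, adjusted p = 0.159 with an estimated correlation). Chemokines and cytokines were higher in 10 and lower in 2 of 30 (11 and 2 adjusted over the list alone, camera adjusted p 0.00549, adjusted p = 0.184 with an estimated correlation). Cxcl10 differed by 0.92 ± 0.12. B and plasma cell markers were higher in 4 of 12 (4 and 0 adjusted over the list alone, camera adjusted p 0.00867, adjusted p = 0.159 with an estimated correlation). The immunoglobulin joining chain gene Jchain differed by 1.82 ± 0.13. NADPH oxidase genes were higher in 5 of 10 (5 and 0 adjusted over the list alone, camera adjusted p 0.0106, adjusted p = 0.154 with an estimated correlation).

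Thick ascending limb markers were lower in uninephrectomized SBH/y in 9 and higher in 1 of 12 by either adjustment, over all probe sets or adjusted over the list alone (camera adjusted p 1.16e-05, adjusted p = 0.0701 with an estimated correlation). Casr differed by -1.37 ± 0.06. Distal convoluted and connecting tubule markers were lower in 9 and higher in 0 of 14, again by either adjustment (camera adjusted p 2.26e-05, adjusted p = 0.0701 with an estimated correlation). The tissue kallikrein Klk1 differed by -0.73 ± 0.06. Intercalated cell markers were lower in 7 of 12 by either adjustment (camera adjusted p 6.16e-05, adjusted p = 0.0701 with an estimated correlation). The anion exchanger Slc4a1 differed by -0.59 ± 0.07. Podocyte markers were lower in 9 and higher in 2 of 24 (10 and 3 adjusted over the list alone, camera adjusted p 0.00802, adjusted p = 0.243 with an estimated correlation). Of this list, Mme differed by -0.51 ± 0.04 and synaptopodin, Synpo, by -0.45 ± 0.06. In SBN/y with both kidneys Mme lay between 10.64 and 10.94, against a mean of 6.62 for Nphs1. Which kidney cells gave the Mme values was not tested. Endothelial markers were lower in 9 and higher in 2 of 19 by either adjustment (camera adjusted p 0.00867, adjusted p = 0.259 with an estimated correlation). The VEGF receptor Kdr differed by -0.41 ± 0.05. Oxidative phosphorylation genes were lower in 30 and higher in 1 of 46 (33 and 1 adjusted over the list alone, camera adjusted p 2.14e-09, adjusted p = 0.154 with an estimated correlation).

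Of the remaining lists past camera, sodium and chloride transport was lower in 16 and higher in 4 of 33 by either adjustment (camera adjusted p 0.000963, adjusted p = 0.154 with an estimated correlation). The kinase Stk39 differed by -0.50 ± 0.05. Collecting duct markers were lower in 7 and higher in 1 of 13 (8 and 1 adjusted over the list alone, camera adjusted p 0.00244, adjusted p = 0.24 with an estimated correlation), and inner medulla markers lower in 7 of 15 (8 adjusted over the list alone, camera adjusted p 0.00386, adjusted p = 0.296 with an estimated correlation). Proximal tubule markers were higher in 16 and lower in 3 of 33 (17 and 3 adjusted over the list alone, camera adjusted p 5.53e-05, adjusted p = 0.16 with an estimated correlation). Agmat differed by 1.53 ± 0.06. Immediate early and heat shock genes were higher in 9 and lower in 1 of 27 by either adjustment (camera adjusted p 0.0189, adjusted p = 0.154 with an estimated correlation). Myc differed by 1.18 ± 0.13. Clock genes were higher in 10 and lower in 2 of 17 (11 and 4 adjusted over the list alone, camera adjusted p 0.0246, adjusted p = 0.243 with an estimated correlation). In the kidney panel, Spp1 was higher by 0.75 ± 0.10, Col3a1 by 0.63 ± 0.10, Agt by 0.47 ± 0.12, the cytokine Tgfb1 by 0.44 ± 0.07 and Col1a1 by 0.32 ± 0.09. Kl differed by -0.51 ± 0.15, Nphs1 by -0.33 ± 0.10 (a second probe set by -0.19, not called) and the growth factor Egf by -0.22 ± 0.04. Lcn2, Clu, Umod and Ccn2 were not called, with differences from -0.10 for Clu to 0.07 for Ccn2. In all, 23 of 38 lists passed camera and 0 did so with an estimated correlation, of which 12 had an unadjusted p under 0.05. With the clock gene score of each array as a covariate in limma, an alternative chosen after seeing the data, 3916 probe sets were called in place of 6663.

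Uninephrectomy in SBN/y was followed by few called changes. Ccn2, the connective tissue growth factor, rose by 0.59 ± 0.07 on the log2 scale (7 arrays per group) and its relative Ccn1 by 0.62 ± 0.13. The urea cycle gene Cps1 rose by 1.14 ± 0.21, the mitochondrial carrier Slc25a25 by 0.93 ± 0.17, the cytokine signalling suppressor Cish by 0.83 ± 0.15 and the transcription factor Foxq1 by 0.79 ± 0.18. The insulin receptor substrate Irs2 rose by 0.69 ± 0.13 and Calb1 by 0.54 ± 0.11. Klk1c4, a member of the tissue kallikrein family, fell by 1.71 ± 0.21, from a mean of 7.33 ± 0.34 to 5.63 ± 0.44 (SD, n = 7), the lower mean below the array medians. Of lipid synthesis genes, Scd, which is also on the adipose tissue list, fell by 1.97 ± 0.41, Thrsp fell by 1.51 ± 0.33 and Fasn fell by 0.78 ± 0.13. The other largest falls were those of Spp2, Stc2, Dnah7 and Lgals2, with log2 changes of -0.62 ± 0.11, -0.59 ± 0.13, -0.50 ± 0.10 and -0.50 ± 0.10. Tissue kallikreins are close in sequence, and a probe set can bind more than 1 of them. In limma, 69 probe sets rose and 75 fell, for 41 and 45 genes, with an adjusted p of 5.49e-05 for Ccn2 and for Klk1c4.

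Heat shock and immediate early genes rose as a group, with 5 of 27 members up and 0 down (7 and 0 adjusted over the list alone). The camera adjusted p was 3.24e-05, with 0.0269 for this list with an estimated correlation. Hspa1a, an inducible heat shock protein, rose by 0.36 ± 0.07, its cochaperone Dnajb1 by 0.35 ± 0.06 and Jun by 0.47 ± 0.09. The unfolded protein response had 2 of 28 members up (4 adjusted over the list alone), Manf at 0.28 ± 0.06 and Hspa5 at 0.24 ± 0.06. For the unfolded protein response the camera adjusted p was 5.8e-07, against an adjusted p = 0.0563 with an estimated correlation. Proximal tubule markers fell in 4 of 33 cases and rose in 0 (11 and 1 adjusted over the list alone), among them the phosphate transporter Slc34a3, which fell by 0.41 ± 0.07, and the glucose transporter Slc5a2, which fell by 0.37 ± 0.07. For proximal tubule markers the camera adjusted p was 1.2e-07, against an adjusted p = 0.103 with an estimated correlation. Distal convoluted and connecting tubule markers rose in 2 of 14 (5 adjusted over the list alone), with Slc8a1 at 0.44 ± 0.07, and thick ascending limb markers in 1 of 12 (3 adjusted over the list alone), with Cldn16 at 0.22 ± 0.05. Their camera adjusted p was 0.000378 and 3.73e-05, and for both the adjusted p = 0.087 with an estimated correlation. Hypoxia and glycolysis genes rose in 2 of 34 (3 adjusted over the list alone, camera adjusted p 0.0416, adjusted p = 0.462 with an estimated correlation).

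Of 20 cholesterol synthesis genes 0 were called over all probe sets and 3 were lower when adjusted over the list alone, while the list as a whole was lower in camera (adjusted p 3.24e-05, adjusted p = 0.246 with an estimated correlation). Of 15 adipose tissue markers 1, Scd, was called lower, a call that ended with 1 array left out as given below, and 4 were lower when adjusted over the list alone (camera adjusted p 0.000838, adjusted p = 0.462 with an estimated correlation), with Ucp1 at -1.27 ± 0.38, not called. The adipose list stands for tissue that a kidney sample could carry along. The amount of such tissue in each sample was not measured, so its part in these falls cannot be told. Of the kidney panel only Ccn2 was called in SBN/y, and Havcr1 had a log2 change of 0.54 ± 0.23 (limma adjusted p 0.474), Nphs1 of -0.07 ± 0.10 and Spp1 of 0.10 ± 0.10. The other 9 panel genes changed by -0.05 (Tgfb1) to 0.15 (Egf). The count of 144 was 9 without the 8 arrays numbered 6 or 7, an alternative added after seeing the data, and 60 with only the SBN/y arrays in the fit. It was 280 with the replicate block, 275 with the SD of each array as a covariate and 225 with array quality weights. It dropped to 69, 72, 87, 95, 91, 79 and 62 without SBN/y replicate 3 or 5 with both kidneys or SBN/y uninephrectomized replicate 2, 3, 4, 5 or 7, in that order. Leaving out SBN/y uninephrectomized replicate 3 ended the call of Ccn1 (0.51 to 0.68 over all such fits). Leaving out SBN/y replicate 5 with both kidneys or SBN/y uninephrectomized replicate 5 ended that of Scd (-2.36 to -1.74). The call of Dnah7 (-0.55 to -0.42) ended without SBN/y replicate 3 with both kidneys or SBN/y uninephrectomized replicate 7, and that of Lgals2 (-0.54 to -0.44) without SBN/y replicate 5 with both kidneys or SBN/y uninephrectomized replicate 2 or 5. Any of 9 arrays ended the calls of Cldn16 (0.20 to 0.24), Foxq1 (0.72 to 0.88), Manf (0.24 to 0.31), Stc2 (-0.70 to -0.52) and Thrsp (-1.77 to -1.33), and any of 16 that of Hspa5 (0.22 to 0.27).

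In SBH/y, uninephrectomy was followed by a rise of Havcr1, the kidney injury molecule of damaged proximal tubules, by 2.79 ± 0.23 on the log2 scale from 4.74 ± 0.26 to 7.53 ± 0.78 (SD, n = 7 arrays per group). The lower mean lies below the array medians, so the size of the rise is that of the deposited values. Spp1 rose by 0.86 ± 0.10, Gpnmb by 1.15 ± 0.11, Ccn2 by 0.61 ± 0.07, Clu by 0.51 ± 0.07, Col1a1 by 0.46 ± 0.09 and Tgfb1 by 0.32 ± 0.07, while Nphs1, which encodes nephrin of the podocyte slit diaphragm, fell by 0.62 ± 0.10. Klk1c4 fell by 2.59 ± 0.21, also to a mean below the array medians. Cps1 rose by 1.55 ± 0.21 and the growth factor Areg by 1.29 ± 0.15. In limma the adjusted p was 4.37e-09 for Havcr1, 2.68e-09 for Klk1c4 and 8.55e-05 for Nphs1, and of the probe sets 1033 rose and 1525 fell, for 690 and 784 genes. Scaling moved this balance, with 1313 and 1462 by quantile normalization and 1491 and 1575 with the SD of each array as a covariate. Of the other panel genes Lcn2 had a log2 change of 0.10 ± 0.09, Col3a1 of 0.30 ± 0.10, Umod of -0.01 ± 0.04, Egf of -0.05 ± 0.04, Kl of 0.00 ± 0.15 and Agt of 0.09 ± 0.12, none called. A second probe set of Col1a1 showed a log2 change of -0.017 and that of Clu one of 0.21, neither called, and that of Nphs1 one of -0.56, which was called.

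**Figure D2:**
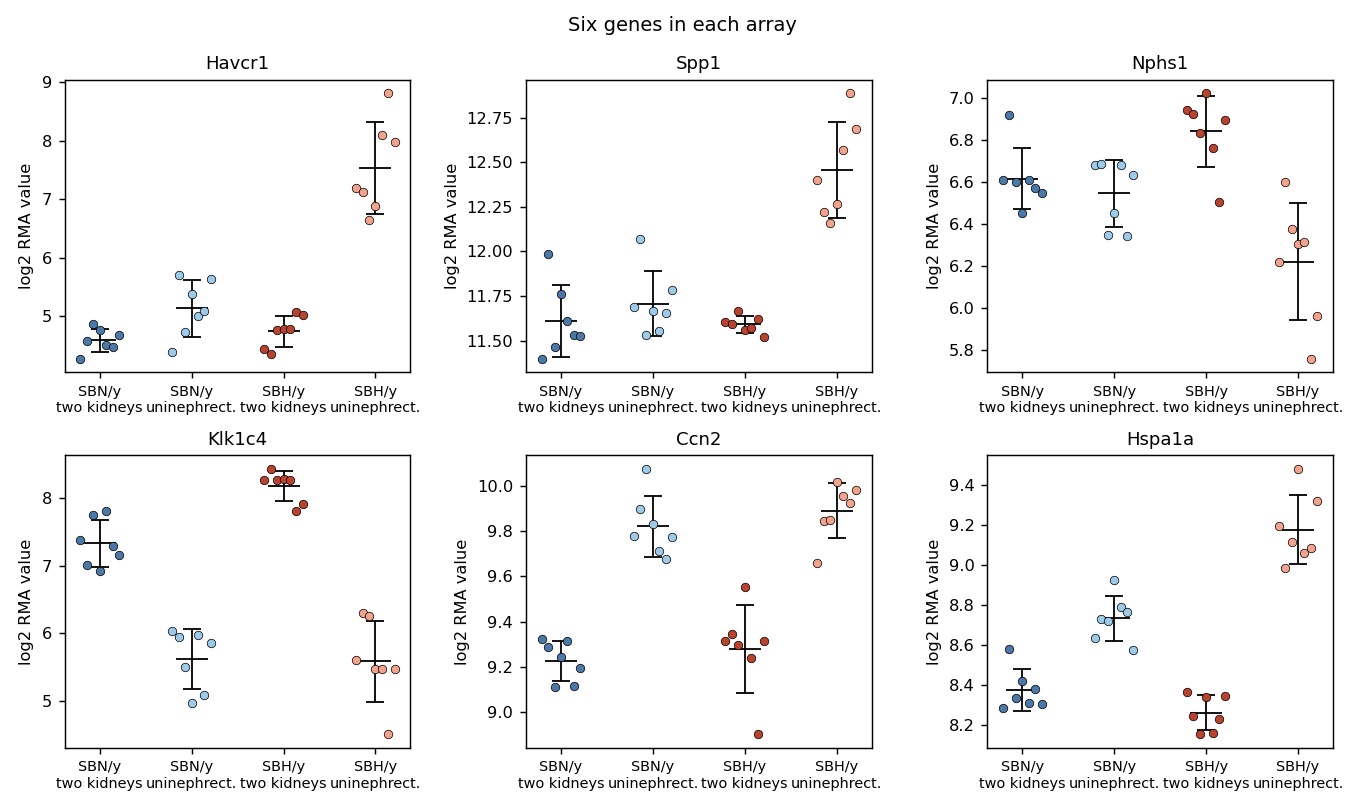
Log2 RMA values (vertical axes) of 6 genes in each array, by group (horizontal axes); points are arrays, horizontal lines group means and whiskers 1 SD (n = 7). Havcr1 lies between 6.64 and 8.81 in uninephrectomized SBH/y and at 5.71 or below in every other array, while Klk1c4 and Ccn2 separate uninephrectomized from arrays with both kidneys in both strains.

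Clock genes were among the largest changes in SBH/y. Dbp rose by 2.05 ± 0.36, Per3 by 1.47 ± 0.29, the deubiquitinase Usp2 by 1.37 ± 0.24, Bhlhe41 by 1.31 ± 0.24, Nr1d2 by 1.30 ± 0.25 and Per2 by 1.29 ± 0.21. Npas2 fell by 2.70 ± 0.34 and Bmal1, their activator in the molecular clock, fell by 2.16 ± 0.33. Of 17 clock genes 10 rose and 4 fell (12 and 4 adjusted over the list alone, camera adjusted p 0.000954, adjusted p = 0.144 with an estimated correlation). The other largest falls were those of Ddit4l, which fell by 2.66 ± 0.39, the monocarboxylate transporter Slc16a1, which fell by 1.68 ± 0.27, Angptl4, which fell by 1.18 ± 0.23, Rnf125, which fell by 1.13 ± 0.22, and osteoprotegerin, Tnfrsf11b, which fell by 1.12 ± 0.19. The clock gene score was 0.525 ± 0.105 (SD, n = 7) in SBH/y with both kidneys and -0.79 ± 0.625 after uninephrectomy, where 6 arrays lay between -1.23 and -0.821 and replicate 2 at 0.587 (exact permutation test, two-sided p = 0.0035, adjusted over 20 tests 0.0544). In SBN/y the scores were 0.0459 ± 0.334 and 0.219 ± 0.505 (exact permutation p = 0.49, adjusted 0.653), with replicate 6 of the uninephrectomized arrays at -0.885. The strains differed in the score with an exact permutation p = 0.00641 with both kidneys (adjusted 0.0544) and 0.0181 after uninephrectomy (adjusted 0.0905). The difference between the 3' and 5' GAPDH control probe sets, a sign of RNA integrity, was 0.54 ± 0.0373 log2 units after uninephrectomy in SBH/y and 0.461 ± 0.0498 with both kidneys (exact permutation p = 0.00816, adjusted 0.0544). In SBN/y it was 0.512 ± 0.041 and 0.445 ± 0.0794 (exact permutation p = 0.0723, adjusted 0.217). For actin it was higher after uninephrectomy by 0.118 in SBN/y and by 0.0704 in SBH/y (exact permutation p = 0.0594 and 0.0758, adjusted 0.217 for each).

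**Figure D3:**
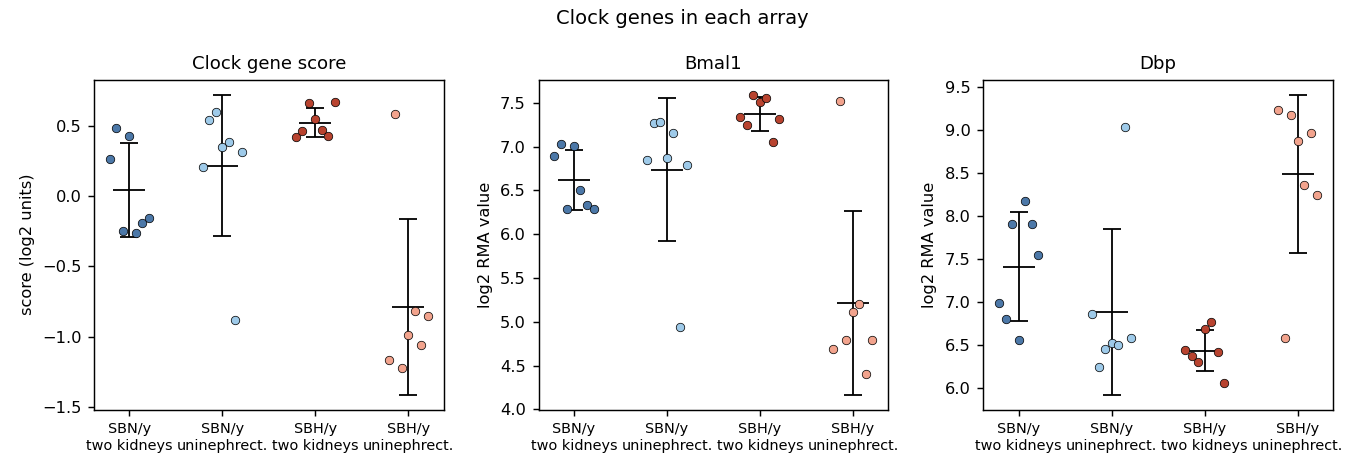
Clock gene score, Bmal1 and Dbp (vertical axes, log2 units) in each array by group (horizontal axes); points are arrays, horizontal lines group means and whiskers 1 SD (n = 7). Replicate 2 of the uninephrectomized SBH/y arrays has a score of 0.587 where the other 6 lie between -1.23 and -0.821, and replicate 6 of the uninephrectomized SBN/y arrays lies at -0.885.

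Genes of the unfolded protein response rose in 15 of 28 cases and fell in 0 (19 and 0 adjusted over the list alone), with the secreted chaperone-like factor Manf at 0.62 ± 0.06, Herpud1 at 0.88 ± 0.10, Sdf2l1 at 0.57 ± 0.08 and the chaperone Hspa5 at 0.36 ± 0.06. Immediate early and heat shock genes rose in 6 of 27 (11 adjusted over the list alone), with Hspa1a at 0.91 ± 0.07, Atf3 at 0.46 ± 0.07 and Dnajb1 at 0.39 ± 0.06. B and plasma cell markers rose in 4 of 12 (7 adjusted over the list alone), led by Jchain at 1.19 ± 0.13. The camera adjusted p of these 3 lists was 3.12e-14, 2.98e-06 and 2.39e-05, and they alone of the 17 lists past the threshold kept it with an estimated correlation, with an adjusted p = 0.00256, 0.00496 and 0.0489. Tubular injury genes rose in 13 and fell in 2 of 31 by either adjustment, over all probe sets or adjusted over the list alone (camera adjusted p 4.91e-06, adjusted p = 0.104 with an estimated correlation). Cell cycle genes rose in 17 of 37 (22 adjusted over the list alone), with the mitotic kinase Cdk1 at 0.46 ± 0.11 and Ube2c at 0.36 ± 0.09. For cell cycle genes the camera adjusted p was 9.37e-09, against an adjusted p = 0.0738 with an estimated correlation. Podocyte markers fell in 10 and rose in 1 of 24 (14 and 4 adjusted over the list alone), with the transcription factor Wt1, which fell by 0.55 ± 0.07, and Ptpro, which fell by 0.42 ± 0.06. For podocyte markers the camera adjusted p was 9.08e-06, against an adjusted p = 0.104 with an estimated correlation. Endothelial markers fell in 4 of 19 (5 adjusted over the list alone), with Kdr at -0.31 ± 0.05. For endothelial markers the camera adjusted p was 1.59e-05, against an adjusted p = 0.122 with an estimated correlation.

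**Figure D4:**
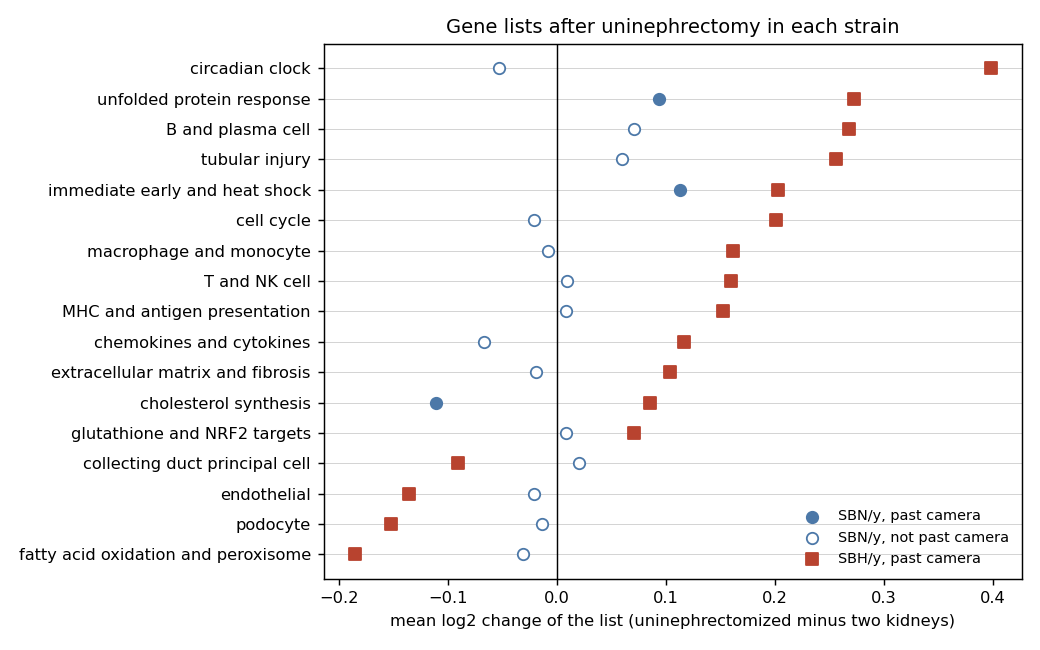
Mean log2 change after uninephrectomy (horizontal axis) of the 17 gene lists past camera in SBH/y (vertical axis), in SBN/y (circles) and SBH/y (squares); filled symbols passed an adjusted p of 0.05 in camera at the preset correlation. The mean is 0.27 in SBH/y and 0.09 in SBN/y for the unfolded protein response, and -0.15 and -0.01 for podocyte markers.

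Fatty acid oxidation and peroxisome genes fell in 11 of 37 cases (20 adjusted over the list alone), with the acyl-CoA synthetase Acsl1, which fell by 0.47 ± 0.07, and the carnitine acyltransferase Crot, which fell by 0.34 ± 0.06. For fatty acid oxidation the camera adjusted p was 2.05e-09, against an adjusted p = 0.18 with an estimated correlation. Matrix and fibrosis genes rose in 13 and fell in 5 of 44 (19 and 6 adjusted over the list alone, camera adjusted p 0.000133, adjusted p = 0.203 with an estimated correlation). Timp1 changed by 0.53 ± 0.08 and the calcification inhibitor Mgp by 0.39 ± 0.06. Macrophage markers rose in 7 of 27 (12 up and 2 down adjusted over the list alone, camera adjusted p 0.000149, adjusted p = 0.309 with an estimated correlation). The receptor gene Csf1r changed by 0.33 ± 0.06 and Mrc1 by 0.61 ± 0.13. T and NK cell markers rose in 7 of 24 (8 adjusted over the list alone, camera adjusted p 0.000205, adjusted p = 0.284 with an estimated correlation). The T cell receptor chain gene Cd3e changed by 0.54 ± 0.07 and Cd3g by 0.52 ± 0.08. Antigen presentation genes rose in 6 of 26 (11 adjusted over the list alone, camera adjusted p 6.81e-05, adjusted p = 0.316 with an estimated correlation). RT1-DMa changed by 0.49 ± 0.07. SBH/y uninephrectomized replicate 2, with a clock gene score of 0.587, lay below the other 6 arrays of its group for Csf1r (7.33 against 7.65 to 7.75), Cd3g (4.99 against 5.37 to 5.63) and RT1-DMa (7.15 against 7.46 to 7.67). It did so for Herpud1 of the unfolded protein response too (9.52 against 9.93 to 10.10). The log2 changes of these 4 genes were 0.18 ± 0.09, 0.32 ± 0.11, 0.33 ± 0.10 and 0.43 ± 0.10 with the clock gene score as a covariate, none called. Chemokines and cytokines rose in 5 and fell in 2 of 30 (6 and 2 adjusted over the list alone, camera adjusted p 0.0154, adjusted p = 0.306 with an estimated correlation). Cholesterol synthesis genes rose in 1 and fell in 1 of 20 (4 and 1 adjusted over the list alone, camera adjusted p 0.0279, adjusted p = 0.472 with an estimated correlation). NRF2 target genes rose in 8 and fell in 2 of 44 (9 and 5 adjusted over the list alone, camera adjusted p 0.0296, adjusted p = 0.472 with an estimated correlation). Gstp1 changed by 0.55 ± 0.07 and the heme oxygenase Hmox1 by 0.62 ± 0.09. Collecting duct markers rose in 0 and fell in 4 of 13 (0 and 4 adjusted over the list alone, camera adjusted p 0.0296, adjusted p = 0.472 with an estimated correlation).

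With the clock gene score as a covariate, 73 probe sets were called in SBH/y in place of 2558, at a median standard error 1.51 times as large, and without the 8 arrays numbered 6 or 7 there were 1293; both alternatives were added after seeing the data. With that covariate the log2 change of Havcr1 was 2.75 ± 0.36, of Klk1c4 -2.28 ± 0.31, of Ccn2 0.72 ± 0.11, of Spp1 0.88 ± 0.15, of Hspa1a 0.86 ± 0.10 and of Jchain 1.17 ± 0.20, all called. That of Nphs1 was -0.36 ± 0.14, of Areg 0.63 ± 0.17 and of Slc16a1 -0.13 ± 0.18, not called.

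Averaged over the strains, uninephrectomy was followed by 796 probe sets called up and 1229 called down, for 499 and 622 genes. The largest rises were Havcr1 at 1.67 ± 0.17 (with means below the array medians in both strains with both kidneys), Cps1 at 1.34 ± 0.15, the glutathione transferase gene Gsta3l1 at 0.88 ± 0.13, and Jchain at 0.83 ± 0.09, followed by Usp2 at 0.77 ± 0.17, Per2 at 0.76 ± 0.15, Gadd45g at 0.75 ± 0.18 and Gpnmb at 0.72 ± 0.08. Klk1c4 fell by 2.15 ± 0.14 to means below the array medians, Npas2 fell by 1.37 ± 0.24, Ddit4l fell by 1.20 ± 0.28, and Scd fell by 1.11 ± 0.29. Bmal1 fell by 1.02 ± 0.23, Slc16a1 fell by 0.78 ± 0.19, Thrsp fell by 0.75 ± 0.23 and the neutrophil gene S100a9 fell by 0.72 ± 0.19. Of the panel, Ccn2 rose by 0.60 ± 0.05, Spp1 by 0.48 ± 0.07, Clu by 0.23 ± 0.05 and Col1a1 by 0.21 ± 0.06, and Nphs1 fell by 0.34 ± 0.07. Tgfb1 at 0.14 ± 0.05, Col3a1 at 0.13 ± 0.07, Lcn2 at 0.09 ± 0.06, Umod, Egf, Kl and Agt were not called. The second probe set of Col1a1 had a log2 change of -0.064 and that of Clu one of 0.09, neither called. Only the unfolded protein response, with 18 of 28 members up (21 adjusted over the list alone), and immediate early and heat shock genes, with 11 of 27 up by either adjustment, passed camera with an estimated correlation as well, at an adjusted p of 0.000855 each. Of the other lists, fatty acid oxidation genes fell in 13 of 37 (17 adjusted over the list alone, camera adjusted p 2.09e-08, adjusted p = 0.266 with an estimated correlation) and proximal tubule markers fell in 9 and rose in 2 of 33 (13 and 2 adjusted over the list alone, camera adjusted p 9.68e-05, adjusted p = 0.269 with an estimated correlation). The remaining 11 lists past camera were tubular injury, B and plasma cell, cell cycle, T and NK cell, antigen presentation, macrophage, matrix and clock genes, higher as lists, and endothelial, podocyte and adipose markers, lower as lists, with an adjusted p from 0.0705 to 0.443 with an estimated correlation. The count of 2025 was 979 without the arrays numbered 6 or 7 and 503 with the clock gene score as a covariate, and leaving out 1 array ended the calls of Col1a1 (any of 16 arrays, 0.19 to 0.24) and Thrsp (any of 20, -0.88 to -0.66).

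The interaction asked which responses to uninephrectomy differed between the strains. Havcr1 rose more in SBH/y than in SBN/y, by 2.25 ± 0.33 log2 units (limma adjusted p 0.000741), where 3 of the 4 group means lay below the array medians. So did Spp1 by 0.77 ± 0.14, Gpnmb by 0.87 ± 0.15, Clu by 0.54 ± 0.10, Areg by 1.24 ± 0.21 and Col1a1 by 0.49 ± 0.12. The response of Nphs1 differed by -0.55 ± 0.14. The second probe sets of Clu, Col1a1 and Nphs1 had interactions of 0.24, 0.10 and -0.40, none called. The response of Ccn2 differed by 0.02 ± 0.10 (adjusted p 0.978) and that of Klk1c4 by -0.89 ± 0.29 (adjusted p 0.142), neither called. Clock genes made up many of the largest interactions, with Dbp at 2.58 ± 0.51, Nr1d2 at 1.85 ± 0.35, Per3 at 1.85 ± 0.41, Nr1d1 at 1.74 ± 0.44, Bhlhe41 at 1.30 ± 0.34, and Npas2 at -2.67 ± 0.48 and Bmal1 at -2.27 ± 0.47. Beside them were Ddit4l at -2.93 ± 0.55, Slc16a1 at -1.79 ± 0.39, Rnf125 at -1.47 ± 0.31, Nfil3 at -1.30 ± 0.31 and Tnfrsf11b at -1.29 ± 0.27. Ucp1 of the adipose tissue list at 2.33 ± 0.54 and the melanocyte gene Mlana at -1.33 ± 0.21 completed them. In all, 185 probe sets had a positive and 254 a negative interaction, for 137 and 156 genes. Of the probe sets called after uninephrectomy in either strain, 61 were called in both in the same direction and 4 in the opposite direction, where independent calls would share 5.981 in the same direction. The log2 changes of the strains correlated across all probe sets with r = 0.251, and the group means behind these changes share no arrays. The calls in both strains do share a variance per probe set, fitted to all arrays. The number for independent calls is therefore only a rough reference, and the excess over it was not tested.

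Of the lists, 5 of 24 podocyte markers had a negative interaction and 0 a positive one (8 and 0 adjusted over the list alone, camera adjusted p 3.92e-05, adjusted p = 0.167 with an estimated correlation). Wt1 had an interaction of -0.58 ± 0.10. Tubular injury genes had 6 positive and 1 negative interactions among 31 (8 and 2 adjusted over the list alone, camera adjusted p 0.000683, adjusted p = 0.2 with an estimated correlation). The unfolded protein response had 4 positive among 28 (9 adjusted over the list alone, camera adjusted p 1.49e-05, adjusted p = 0.149 with an estimated correlation). Herpud1 had an interaction of 0.71 ± 0.14. The cell cycle had 1 positive among 37 (9 adjusted over the list alone, camera adjusted p 4.48e-09, adjusted p = 0.149 with an estimated correlation). Fatty acid oxidation had 2 negative among 37 (5 adjusted over the list alone, camera adjusted p 1.89e-05, adjusted p = 0.243 with an estimated correlation). Acsl1 had an interaction of -0.55 ± 0.10. Of single members of other lists, tissue kallikrein Klk1 of the distal tubule had an interaction of -0.49 ± 0.08, Timp1 of the matrix list 0.61 ± 0.11, Irf8 of the interferon list 0.52 ± 0.10 and Cd3e of the T cell list 0.45 ± 0.10. The transporter Abcc4 of the NRF2 list had one of 0.40 ± 0.07 and the mineralocorticoid receptor Nr3c2 of the collecting duct list -0.38 ± 0.07. Positive and negative interactions of members were 0 and 1 of 14 in the distal tubule list, 3 and 1 of 44 in the matrix list, 2 and 0 of 36 in the interferon list, 2 and 0 of 24 in the T cell list, 2 and 0 of 44 in the NRF2 list, and 0 and 2 of 13 in the collecting duct list. Adjusted over the list alone they were 0 and 1, 8 and 1, 2 and 0, 5 and 0, 5 and 0, and 0 and 4 in the same order. In all 21 of 38 lists passed camera and 0 did so with an estimated correlation, of which 9 had an unadjusted p under 0.05, and the adjusted p of the other 16 lay between 0.167 and 0.557 with an estimated correlation. With the clock gene score as a covariate, limma called 0 interactions (1540 probe sets with an unadjusted p under 0.05), the interaction of Havcr1 being 2.201 ± 0.458, not called at this larger standard error. The count was 117 without the arrays numbered 6 or 7 and 870 without SBH/y uninephrectomized replicate 2. It was 812 with the replicate block, 744 with the SD of each array as a covariate and 899 with array quality weights. Leaving out 1 array ended the calls of Bhlhe41 (any of 21 arrays, 1.22 to 1.52), Col1a1 (any of 18, 0.42 to 0.54), Nphs1 (any of 16, -0.61 to -0.47) and Nr1d1 (any of 17, 1.54 to 1.99).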

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

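The tests with the SD of each array as a covariate and of the phase direction of clock genes, and the splits within sample numbers, were chosen only after the result was seen. Leaving out the 8 arrays numbered 6 or 7 and the clock gene score as a covariate were added after seeing the data, before their values were computed.

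The arrays were split 100 times into groups of the same sizes, the real split included. In 5 of the 6 comparisons only 1, the real one, called as many probe sets. That is the smallest share 100 splits can give, so chance alone is an unlikely source of these counts but is not excluded. The real counts and the highest of the other splits were 5570 and 2225 for the strain difference with both kidneys, 6663 and 2073 for that after uninephrectomy, 144 and 2 for uninephrectomy in SBN/y, 2558 and 112 in SBH/y, and 2025 and 3 for the average over the strains. For the interaction 2 of the 100 splits, the real one included, called as many, with 439 in the real split and 1242 in the highest other one, a share under 0.05. These splits did not keep the sample numbers together, and what lay behind the split with several times the real count was not tested. Those for the interaction exchanged kidney states within each strain, which also removed an effect of uninephrectomy shared by the strains or could turn it into an apparent interaction. They therefore did not test for equal effects in the strains. In splits that exchanged groups only within a number, 64 for each difference between 2 groups and 100 for the average and the interaction, only 1, the real one, called as many. The highest other counts there were 2468 and 3255 for the strain differences with both kidneys and after uninephrectomy, 16 in SBN/y, 1715 in SBH/y, 1081 for the average and 4 for the interaction. With the numbers kept, chance alone is thus also an unlikely source, within the 64 or 100 splits run, but is not excluded.

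Samples far from the others of their group were found by the gap to the nearest sample as a share of the group's range, given here as a ratio. Of 524 tests of a group, 61 had such a sample, where about 1 in 20 groups, or 26, would by chance. SBH/y uninephrectomized replicate 2 lay above the others for Bmal1 0.745, Ddit4l 0.755, Nfil3 0.688, Npas2 0.729, Rnf125 0.766, Slc16a1 0.741, Slc8a1 0.732 and the clock gene score 0.777 and below them for C1qc 0.641, Cd3g 0.595, Csf1r 0.767, Dbp 0.627, Herpud1 0.703, Nr1d2 0.747, Per2 0.745, Per3 0.786, RT1-DMa 0.596 and Usp2 0.748. SBN/y uninephrectomized replicate 6 lay above the others for Bhlhe41 0.619, Dbp 0.775, Herpud1 0.571 and Per3 0.731 and below them for Acsl1 0.578, Agt 0.623, Bmal1 0.789, Ddit4l 0.588, Nfil3 0.582, Npas2 0.696, Slc16a1 0.569 and the clock gene score 0.736. SBN/y replicate 2 with both kidneys lay above the others for Csf1r 0.589, Nphs1 0.664 and S100a9 0.761 and below them for Col1a1 0.576, Gstp1 0.597, Ly6i 0.741, Mme 0.687 and Usp2 0.614. SBH/y replicate 4 with both kidneys lay above the others for Lyz2 0.61, RT1-Ba 0.649 and Slc25a25 0.57 and below them for Casr 0.652. SBH/y uninephrectomized replicate 6 lay above the others for Clu 0.571 and Lcn2 0.575 and below them for Ptpro 0.597 and Uqcrq 0.655. SBN/y uninephrectomized replicate 2 lay above the others for Thrsp 0.627 and below them for Mpv17l 0.577 and RT1-Ba 0.704. Of single genes, Cd3g in SBN/y uninephrectomized replicate 7 (0.764), Lcn2 in SBN/y uninephrectomized replicate 7 (0.73), Slc25a25 in SBN/y replicate 1 with both kidneys (0.694), Kl in SBN/y uninephrectomized replicate 5 (0.619), Mlana in SBN/y replicate 5 with both kidneys (0.671), Mmp9 in SBH/y replicate 3 with both kidneys (0.616) and RT1-CE12 in SBN/y replicate 4 with both kidneys (0.7) lay above the others of the group. The values of Kl in SBN/y replicate 1 with both kidneys (0.652), Kif11 in SBH/y uninephrectomized replicate 4 (0.678), Timp1 in SBN/y replicate 7 with both kidneys (0.671), Ucp1 in SBN/y replicate 3 with both kidneys (0.635) and Umod in SBH/y uninephrectomized replicate 7 (0.595) lay below them.

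A second set of results differed between the strains in their response to uninephrectomy, by an interaction past the threshold in limma, for 439 probe sets in all and for 44 of the 126 genes named. The positive ones were Abcc4 0.40, Areg 1.24, Asns 0.45, Atf3 0.48, Bhlhe41 1.30, Cd3e 0.45, Clu 0.54, Col1a1 0.49, Cxcl10 0.77, Dbp 2.58, Fasn 0.89, Fdps 0.40, Gpnmb 0.87, Havcr1 2.25, Herpud1 0.71, Hspa1a 0.55, Irf8 0.52, Jchain 0.71, Nr1d1 1.74, Nr1d2 1.85, Oacyl 0.81, Per3 1.85, RT1-DMa 0.42, Sdf2l1 0.44, Spp1 0.77, Timp1 0.61 and Ucp1 2.33. The negative ones were Acsl1 -0.55, Bmal1 -2.27, Col17a1 -0.50, Crot -0.45, Ddit4l -2.93, Klk1 -0.49, Mlana -1.33, Mme -0.25, Nfil3 -1.30, Npas2 -2.67, Nphs1 -0.55, Nr3c2 -0.38, Ptpro -0.36, Rnf125 -1.47, Slc16a1 -1.79, Tnfrsf11b -1.29 and Wt1 -0.58.

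Uninephrectomy was followed by more called probe sets in SBH/y than in SBN/y, 2558 against 144. Without the 8 arrays numbered 6 or 7 the SBH/y count was 144 times the SBN/y count (1293 against 9), with the SD of each array as a covariate it was 11.1 times as high (3066 against 275), and the mean squared log2 change less its squared standard error was 4.91 times as large in SBH/y (0.0151 against 0.00308), so these values argue against the sample numbers, the value range of the arrays and a larger spread among SBN/y arrays as the whole cause. With the clock gene score as a covariate the order turned, with 73 calls in SBH/y and 150 in SBN/y, where the standard error in SBH/y was 1.51 times as large at the median. A different clock phase in the uninephrectomized SBH/y arrays may therefore account for part of the difference in counts, and RNA integrity was not tested as a cause. The difference between 3' and 5' GAPDH probe sets was higher after uninephrectomy by 0.0793 in SBH/y and by 0.0666 in SBN/y. A stronger response of the hypertension-prone strain stays open as the biological explanation.

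Clock genes were among the largest changes after uninephrectomy in SBH/y, and 100% of the 12 core clock genes measured moved in the direction of a phase shift, 10 of them called. Kidneys taken at another phase of the day would give these directions, but so could a clock altered by uninephrectomy. The direction test, written after these calls were seen, cannot tell them apart. SBH/y uninephrectomized replicate 2 (0.587) was placed by its score among SBH/y arrays with both kidneys (0.422 to 0.669). SBN/y uninephrectomized replicate 6 (-0.885) lay below the SBN/y arrays with both kidneys (-0.262 to 0.484) and within the range of the other uninephrectomized SBH/y arrays (-1.225 to -0.821). For the 2535 other called probe sets, the log2 changes with the clock gene score as a covariate had a slope of 0.656 on those without it (0.601 to 0.785 with 1 array left out), between the bounds of 0.5 and 0.8 set beforehand. The share of these calls that comes from phase therefore cannot be told apart from a response to uninephrectomy, since the score nearly separates the 2 SBH/y groups and the labels give no time of killing. A clock altered by uninephrectomy in SBH/y kidneys stays open as the biological explanation and was not tested.

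Strain differences rest on probes that may cover sequence variants between the strains. Among genes with a second probe set, it moved the same way for 81.4% of 1040 called strain differences with both kidneys and for 88% of 523 called uninephrectomy effects in SBH/y, a gap of 6.51 percentage points, between the bounds of 5 and 10 set beforehand. For the strain difference after uninephrectomy, which the test did not name, the share was 83.5% of 1269, a gap of 4.42 points, and 80% of 40 at a change of at least 1 log2 unit. The second probe set was itself called in the opposite direction for 26 and 28 of these strain differences with both kidneys and after uninephrectomy, and for 1 uninephrectomy effect in SBH/y. For strain differences with both kidneys of at least 1 log2 unit the share was 84.6% of 39 genes (95% exact interval 69.5 to 94.1), between the bounds of 60 and 90. An earlier form of the test, which left out dim second probe sets without having been set out beforehand, gave a gap of 8.14 points and a share of 85.7%, also between the bounds. Variants under the probes therefore cannot be told apart from expression for part of the strain differences, since no strain sequences were used here, and inherited differences in expression stay open as the biological explanation.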

How the results depend on the processing

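Leaving out the 8 arrays numbered 6 or 7, the SD of each array as a covariate and the clock gene score as a covariate were chosen after seeing the data, and the other alternatives were planned. Where no reason is given, the cause was not tested. Another background correction and a slide or scan batch as a block were not run, since no scanner files were used here and the labels name no batch.

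Quantile normalization, median centring, leaving out the dimmest 40% of probe sets and trended and robust variance moderation kept each of the 6 counts of called probe sets within 1.5 times its reported value. Array quality weights gave 225 calls for uninephrectomy in SBN/y and 899 interactions. With only the groups compared in the fit, the SBN/y count was 60, with fewer arrays behind each variance. With 1 probe set per gene the counts were 3318 and 4116 for the strain differences with both kidneys and after uninephrectomy and 1328 for the average over strains, since fewer probe sets were tested.

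The arrays numbered 6 or 7 were left out because they deviated together in all 4 groups, with correlations of 0.135 to 0.586 between any 2 of them from different groups. Of 42 pairs of the same number and different groups, 24 had a correlation over 0.1, and 7654 probe sets differed between numbers 6 and 7 and numbers 1 to 5. The labels name no batch, and whether 1 lies behind this was not tested. Without these 8 arrays, which leaves fewer samples, the counts were 9 in SBN/y, 1293 in SBH/y, 979 for the average and 117 for the interaction. With the SD of each array as a covariate they were 275 in SBN/y and 744 for the interaction. With the clock gene score as a covariate they were 3916 for the strain difference after uninephrectomy, 73 in SBH/y, 503 for the average and 0 for the interaction in limma (1540 at an unadjusted p under 0.05). The covariate raised the standard error in SBH/y by its overlap with the groups, and no value is given for core clock genes, from which the score was made.

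With the replicate block, which takes the sample number as a factor, the counts were 280 in SBN/y and 812 for the interaction, and the cause was not tested. The labels do not say what the numbers share, and 14 of 28 arrays correlated most on average, among arrays of other groups, with those of their own number.

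Leaving out 1 array in turn gave 4841 to 6528 calls for the strain difference with both kidneys, 6095 to 6955 for that after uninephrectomy, 62 to 167 in SBN/y, 1925 to 3145 in SBH/y, 1624 to 2450 for the average and 306 to 870 for the interaction. The 62 came without SBN/y uninephrectomized replicate 7 and the 870 without SBH/y uninephrectomized replicate 2. In SBN/y the count was also 69 and 72 without replicates 3 and 5 with both kidneys, and 87, 95, 91 and 79 without uninephrectomized replicates 2, 3, 4 and 5.

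Of the gene lists past camera, 0 remained past it with an estimated correlation for both strain differences and for the interaction (5, 12 and 9 lists at an unadjusted p under 0.05), 1 in SBN/y, 3 in SBH/y and 2 for the average, and fry called 5 in SBN/y.

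Scaling moved the balance of rises and falls. Against 1033 and 1525 in SBH/y there were 1313 and 1462 with quantile normalization, 1152 and 1269 with median centring and 1491 and 1575 with the SD of each array as a covariate. For the average over strains 796 and 1229 became 1042 and 1190, 899 and 992, and 1246 and 1338 in the same order. With that covariate the higher and lower counts of the strain difference changed from 2991 and 2579 to 2953 and 3071 with both kidneys, and from 3454 and 3209 to 3867 and 3980 after uninephrectomy.

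Other probe sets were run as an alternative only for the kidney panel, where the direction of a called gene was reversed by that of Col1a1, with -0.017 in SBH/y and -0.064 for the average. In 7 further results of the panel the other probe set kept the direction but was not called. Outside the panel, RT1-Ba differed between the strains with both kidneys by 2.02 and its second probe set by -1.19, called in the opposite direction. With the clock gene score as a covariate the strain difference after uninephrectomy was reversed for Ddit4l (0.99), Rnf125 (0.54), Slc16a1 (0.92) and Usp2 (-0.064), the effect in SBH/y for Nfil3 (0.40) and Rnf125 (0.13), and for Nfil3 also the average (0.38) and the interaction (0.048). Among the single gene results, the call was lost in 141 cases with that covariate and in 92 without the 8 arrays, against 7 with quantile normalization, 3 with median centring, 9 with trended and robust moderation, 5 with array weights and 1 with the replicate block. Calls were gained in 36 cases with the replicate block, 31 with array weights and 27 without the dimmest 40% of probe sets. The gains were 14 with the SD of each array, 12 with trended and robust moderation and 9 with quantile normalization. They were 5 with median centring, 5 with the clock gene score and 1 without the 8 arrays. No single gene result was reversed by the other alternatives run on genes, or by leaving out 1 array.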

Other observations

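The neighbour test was set out before its values were computed, and the tests of single genes with the clock gene score, and the genes themselves, were chosen only after the result was seen.

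Genes that differ between inbred strains may lie next to each other on the chromosomes, where a stretch inherited from 1 ancestor holds several. Of 14147 pairs of neighbouring measured genes, 773 had both genes called for the strain difference with both kidneys, 1.18 times the mean of 1000 shuffles of the calls (654.7, highest 716; permutation p = 0.001, the smallest they can give). The uninephrectomy effect in SBH/y, which involves no strain difference, also exceeded its shuffles, with 208 pairs against a mean of 152.3, 1.37 times as many. The rule set beforehand for such stretches was thus met, but the excess is not specific to the strain difference. The test therefore cannot tell whether such stretches exist.

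Some responses in SBH/y passed the threshold with the clock gene score as a covariate too. Gpnmb rose by 0.87 ± 0.15 with it and 1.15 ± 0.11 without it, Clu by 0.53 ± 0.10 and 0.51 ± 0.07, Havcr1 by 2.75 ± 0.36 and 2.79 ± 0.23, Spp1 by 0.88 ± 0.15 and 0.86 ± 0.10, and Klk1c4 had log2 changes of -2.28 ± 0.31 and -2.59 ± 0.21. On all arrays and with 1 array left out, the lowest ratio of the change with the covariate to its standard error was 4.98 for Gpnmb, 4.25 for Clu, 6.32 for Havcr1, 5.12 for Spp1 and, as a fall, 6.47 for Klk1c4. Over all calls outside the clock list the covariate lowered the changes (a slope of 0.656). The 5 genes were picked for passing with the covariate on the same data, so only the fits with 1 array left out could still have failed. These values therefore do not decide whether the clock phase of the samples is the whole cause for the 5 genes. Clock phase as a cause of their changes stays open, as does a response to uninephrectomy, since the labels give no time of killing.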
